A study of Homo sapiens with 5 samples.

How the data were processed

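The data are 5 libraries of A549 cells, an established human lung adenocarcinoma line, which the design text of the series calls ribosome footprint profiling. The labels' protocols also describe fragmented total RNA as an input, and the molecule label of each library reads total RNA, so that these libraries hold footprints rests on the design text, and "footprint" is used here in that sense. Per the labels' protocols, cells were treated with cycloheximide at 100 ug/mL for 15 min, which holds ribosomes on mRNA. Lysates were then digested with RNase I for 5 min, and the fractions with single ribosomes were taken from a sucrose gradient for libraries of RNA depleted of ribosomal RNA. The 4 groups were taken from the labels: a short hairpin (sh) control (1 library), RBMS1 knockdown (2 libraries, sh1088 and sh1196, each with its own hairpin), a control with the name pCDH (1 library) and RBMS1 overexpression with the name R1A (1 library). Nothing in the labels says that the 2 knockdown libraries came from separate cultures beyond their separate hairpins, so p-values measure only the spread between these libraries, which may be technical. Counting intervals cover counting error only, since PCR copies are not independent molecules.

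The estimated counts per gene are the authors' RSEM expected counts, per the file headers. Beside them the authors deposited TPM and FPKM, both scaled by RSEM to the effective gene length, per the file headers. The submitters' processing notes name Bowtie, STAR 2.4.2, RSEM 1.3.1 and DESeq2 with no role for each. The genome build and annotation are not given in the sources used here. The authors also deposited a comparison table for each arm with a mean of normalised counts (a signal per gene), a log2 fold change and p-values, per the file headers. Their count columns equal the sample values exactly (maximum difference 0). For overexpression, 27 gene symbols of that table are turned into dates, so rows were matched by gene identifier. The libraries held between 10327747 and 13980843 expected counts over 58929 genes. Of these identifiers 58656 matched GENCODE release 29 without their version number and 273 did not. Gene coordinates, biotypes, overlaps and GC content were taken from that release, whose build is GRCh38 and may differ from the authors'.

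Expected counts were rounded to whole numbers. RBMS1 knockdown was compared with the sh control by edgeR 4.0.16 (quasi-likelihood test with robust dispersion, TMM scaling, filterByExpr, Benjamini-Hochberg adjustment at 0.05) in R 4.3.3. This fit has 1 residual degree of freedom, and the lone control is assumed to vary like the 2 knockdown libraries. A second edgeR fit over all 5 libraries coded the RBMS1 level as -1, 0 and 1 for knockdown, control and overexpression, with a term for the vector system and 2 residual degrees of freedom. Overexpression against the pCDH control is 1 library against 1, so log2 ratios of TMM-scaled counts are given with an exact conditional 95% counting interval and no p-value. Gene lists fixed before the data were examined (35, of which 32 had at least 3 measured members) were tested with camera of limma 3.58.1 on log2 CPM (prior count 2, preset correlation 0.01), again with an estimated correlation, and with fry. For overexpression each list median was placed among 10000 random lists of the same size matched on expression in 20 bins. DESeq2 1.42.0, limma-voom and glmTreat served as alternatives.

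The genes named were set by a rule written before the data were examined. RBMS1, SLC7A11, SLC3A2, GPX4 and EIF3D are always given. For knockdown the rule takes 12 genes in each direction past the threshold, with mean CPM of at least 5 and the same sign for both hairpins. Where fewer pass, places are filled by the smaller of the 2 absolute hairpin changes. For overexpression it takes 12 genes in each direction by the interval bound nearest to 0, for the level fit 8 in each direction by the same filling rule, and for each list up to 4 members with the smallest knockdown p. Genes that overlap another gene on the same strand are uncertain, because expected counts can be split between them.

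The tests were run on simulated data with 200 changed genes in each of 5 simulations. For the knockdown comparison (14255 genes) edgeR called 2.69% of genes changed 2-fold, 25.4% of those changed 4-fold and 72.4% of those changed 8-fold, with 15 false calls. For the level fit (15186 genes) the shares were 2.99%, 60.3% and 99.4%, with 18 false calls. A list shifted by 0.7 on the log2 scale passed camera in 5 of 5 simulations, and 0 of 155 unshifted lists passed. Genes were drawn independently there, so these simulations cannot show how often lists of correlated members pass without a shift. The counting interval covered the true ratio for 95.8% of 19880 genes simulated with counting error (Poisson) alone, which leaves out spread between libraries. For the 2 hairpins against their shared control, 50 sets of libraries with no effect were drawn at the fitted spread. At the 2-fold limit those libraries gave lists of other sizes than the observed ones (800 and 810 higher genes with 304 in both, and 790 and 766 lower genes with 181 in both), so the overlap was counted again at the observed list sizes, a choice made after the result was seen.

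Beside the settings above, 41 alternatives were planned before the data were examined and 14 were added after. The added ones are a loess correction for GC content (span 0.5, the single setting tried) or length, exchanged controls, a doubled control column, fits without overlapping genes and a rescaled TPM. Translational efficiency was not computed, since total RNA was not analysed here. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.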

Results

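The study, by its design text, profiled ribosome footprints in A549 lung cancer cells in which RBMS1, an RNA-binding protein, was stably depleted or overexpressed. Total expected counts were 11618977 in the sh control, 11739398 in sh1088, 10327747 in sh1196, 13980843 in the pCDH control and 10470077 in the overexpression library. The libraries differed in make-up. Nuclear protein-coding genes took 37.7% of counts in the sh control, 42.2% in sh1088, 66.0% in sh1196, 66.3% in the pCDH control and 62.3% in the overexpression library. AL355075.4, a gene that overlaps the RNase P RNA gene RPPH1, took 30.0%, 20.8%, 7.26%, 15.0% and 11.03% in the same order. The mean fragment length, derived from the difference between gene length and RSEM effective length, was 46.0 nt, 43.4 nt, 46.3 nt, 52.3 nt and 40.9 nt. It was longest in the pCDH control and shortest in the overexpression library, which are compared with each other below.

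RBMS1 (ENSG00000153250.20, chromosome 2, 160272151 to 160493794, minus strand) was examined first, as a check of the labels. It had a footprint CPM of 31.0 (95% counting interval 27.3 to 35.1) in the sh control, 18.3 (15.7 to 21.2) in sh1088 and 13.4 (11.5 to 15.6) in sh1196. It was at 24.7 (22.5 to 27.2) in the pCDH control and 37.0 (33.6 to 40.6) in the overexpression library. In the edgeR fit the knockdown log2 fold change was -0.93 (SE 0.45, edgeR adjusted p = 0.828), lower in 2 of 2 hairpin libraries. The authors' TPM was 1.59 in the sh control against 3.70 and 4.20 in the knockdown libraries, a log2 ratio of 1.31 for their mean, where the median of all genes by TPM was 1.36. FPKM gave 0.70, where the median of all genes was 0.73. TPM rescaled over nuclear protein-coding genes, a unit chosen after seeing the data, gave 14.2 in the sh control, 20.0 in sh1088 and 13.6 in sh1196, a log2 ratio of 0.24 for the mean. For overexpression the log2 ratio was 0.59 (0.40 to 0.79), against 0.12 by TPM, where the median of all genes (computed with a pseudocount of 1) was -0.71. By scaled counts RBMS1 thus moved as the labels say. By TPM and FPKM its knockdown value lay near the median of all genes, and by rescaled TPM it was higher in sh1088. Its overexpression ratio lay at the 51.6th percentile of the 500 genes nearest in GC content. The check therefore does not settle the labels, and the group names below are taken from them.

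**Figure D1:**
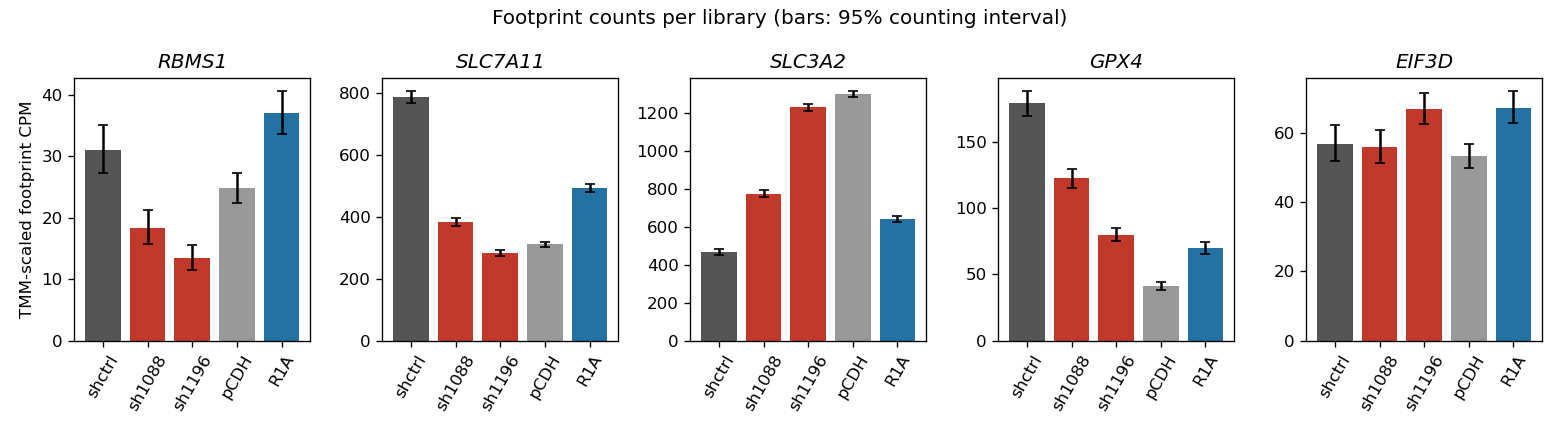
TMM-scaled footprint CPM (y axis) of RBMS1, SLC7A11, SLC3A2, GPX4 and EIF3D in each of the 5 libraries (x axis), with bars for 95% counting intervals. SLC7A11 stands at 788 in the sh control against 383 and 282 in the knockdown libraries, and at 494 in the overexpression library against 311 in the pCDH control.

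The first comparison asked which genes carry more or fewer footprints after RBMS1 knockdown. SLC7A11, the cystine transporter that feeds glutathione synthesis, had a log2 fold change of -1.21 (SE 0.54, edgeR adjusted p = 0.828), with -1.001 in sh1088 and -1.45 in sh1196. Its partner chain SLC3A2 stood at 1.14 (SE 0.65, adjusted p = 0.828), with 0.77 and 1.43. GPX4, the lipid peroxidase that limits ferroptosis, stood at -0.79 (SE 0.50), and EIF3D, a subunit of initiation factor 3, at 0.15 (SE 0.46). None of these passed. With the pCDH control in place of the sh control SLC7A11 stood at 0.11, SLC3A2 at -0.36 and GPX4 at 1.31. By the authors' TPM SLC7A11 was at 17.49 in the sh control, 17.5 in sh1088 and 46.3 in sh1196, and by FPKM at 57.4, 39.9 and 94.3. By TPM it was thus not lower in either hairpin library, and by FPKM it was lower in sh1088 alone. In those units the median log2 ratio of all genes was 1.36 and 0.73 for the mean of the 2 knockdown libraries. SLC7A11 lay below these medians for that mean, and medians for each hairpin were not computed. A fall in both hairpins is therefore shown by scaled counts only.

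Of 14913 genes tested by edgeR, 0 passed an adjusted p of 0.05, and the smallest adjusted p was 0.0794, for AC093010.3. At an unadjusted p under 0.05 there were 876 genes, 487 higher and 389 lower, where 746 would fall there by chance. DESeq2 called 17 and limma-voom 0. Among the genes named by rule, none of which passed, EBI3, a cytokine subunit, stood at 3.74 (SE 0.59) and HBEGF, a ligand of the EGF receptor, at 3.34 (SE 0.75). MEG8 stood at 3.50 (SE 0.73) and INO80B, which overlaps the readthrough gene INO80B-WBP1, at 5.54 (SE 0.69). On the lower side PTP4A1, a phosphatase, stood at -4.25 (SE 0.52), SNHG25 at -3.49 (SE 0.65), PRSS16 at -2.75 (SE 0.58) and GIP, an incretin hormone, at -2.47 (SE 0.57). RNY1, RNY3, RN7SL1 and RN7SL3, small structured RNAs, lay between -4.49 and -2.61. AL356488.2 had 0 counts in the sh control against 148 and 168, and AC093010.3 had 252 against 0 and 0. Of the 24 genes named, 16 overlap another gene on the same strand, as do 5408 of the genes tested. With the pCDH control PTP4A1 stood at 2.24, SNHG25 at 0.83, PRSS16 at 2.30 and INO80B at -0.58.

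By groups, 9 lists passed camera at the preset correlation, while 0 passed with an estimated correlation or by fry. Those 2 tests have little power at 1 residual degree of freedom, so 0 passes there does not decide for or against a list. The estimated correlations of the 9 lists ran from -0.05 (unfolded protein response) to 1 (mitochondrially encoded mRNA). The unfolded protein response list, chaperones and folding enzymes of the endoplasmic reticulum, had a median log2 fold change of 1.10, with 14 of 18 members higher (camera adjusted p = 0.00122, and 0.951 with an estimated correlation). HSPA5, the main chaperone of that compartment, stood at 1.97 (SE 0.79), CRELD2 at 1.68 (SE 0.49), MANF at 1.55 (SE 0.53) and PDIA4 at 1.49 (SE 0.61). The list also holds the transcription factor XBP1, the degradation factors EDEM1, SEL1L and HERPUD1, and SEC61B of the translocon. In the authors' deposited comparison the members below 0 were XBP1 at -0.99, SEC61B at -0.54, DNAJB9 at -0.40 and EDEM1 at -0.25. The G2/M list had a median of 0.77 with 23 of 24 higher (camera adjusted p = 0.00204), among them BUB1 at 1.64 and NUSAP1 at 1.25, and stood at 0.29 in sh1088 and 1.14 in sh1196. The S phase list had 0.64 with 21 of 23 higher (camera adjusted p = 0.00904), among them CDT1 at 1.79 and MCM6 at 1.83, and stood at 0.28 and 0.90 in the same order. Lower were the small ribosomal proteins (median -0.51, 28 of 32 lower, camera adjusted p = 0.00257), with RPS18 at -1.20 and RPS20 at -1.34, and the large ones (median -0.27, 36 of 44 lower, camera adjusted p = 0.00904), with RPLP0 at -1.28. Lower too were mitochondrially encoded mRNA (median -0.65, 12 of 13 lower, camera adjusted p = 0.0124), replication histones (-0.42, 11 of 15, camera adjusted p = 0.0444), small noncoding RNA (-0.79, 7 of 10, camera adjusted p = 0.00499) and ATF4 targets (-0.25, 19 of 30, camera adjusted p = 0.0485). The medians in sh1088 and sh1196 were -0.10 and -1.72 for mitochondrial mRNA, -0.12 and -0.70 for histones, -0.42 and -1.38 for small noncoding RNA and -0.31 and -0.44 for ATF4 targets. Among ATF4 targets, CHAC1 stood at -1.75 (SE 0.45) and ALDH1L2 at -1.31 (SE 0.46). With library size scaling the median of all genes moved from 0.03 to 0.53, and the medians of small ribosomal proteins (0.02), large ribosomal proteins (0.27), histones (0.09) and ATF4 targets (0.25) turned positive while lying below it (camera adjusted p = 0.0422, 0.104, 0.162 and 0.162). Over these lists 0 members were called over all genes tested, and 6 members across all lists were called adjusted over the list alone. With the pCDH control the unfolded protein response median was 0.54 (camera adjusted p = 0.0996), G2/M was at -0.00166 (camera adjusted p = 0.818) and S phase at -0.34, while both ribosomal lists, mitochondrial mRNA, histones, small noncoding RNA and ATF4 targets turned to positive medians. Against that control 8 lists passed camera at the preset correlation. ATF4 targets (0.77, camera adjusted p = 0.0306) and small ribosomal proteins (0.54, camera adjusted p = 0.0396) then lay higher, as did lists that had not passed: NF-kB inflammation (1.65, camera adjusted p = 1.92e-06), proteasome (0.67, camera adjusted p = 0.0109), nuclear oxidative phosphorylation (0.66, camera adjusted p = 0.023) and interferon response (0.86, camera adjusted p = 0.0396). Cholesterol synthesis (-0.48, camera adjusted p = 0.023) and immediate early genes (-0.69, camera adjusted p = 0.0396) lay lower.

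The other lists tested in knockdown did not pass. Their medians were 0.01 for ferroptosis suppressors, -0.00478 for ferroptosis promoters, 0.01 for NRF2 targets, 0.14 for eIF3 subunits, -0.27 for other translation factors and 0.03 for nuclear oxidative phosphorylation genes. Glycolysis stood at 0.06, cholesterol synthesis at 0.42, fatty acid synthesis at -0.04, p53 targets at 0.25, interferon response at -0.19, NF-kB inflammation at 0.11 and hypoxia at 0.39. Mesenchymal genes stood at 0.66 (camera adjusted p = 0.0557), epithelial genes at 0.06, lung lineage at -0.31, cytoskeleton and adhesion at 0.51, proteasome at 0.17 and heat shock chaperones at 0.30. Immediate early genes stood at 0.09, the RBMS family at -0.93, nuclear noncoding RNA at -0.31 and HEK or neural markers at 0.01. Ferroptosis suppressors, NRF2 targets, nuclear oxidative phosphorylation, epithelial genes and HEK or neural markers had positive medians while camera placed them lower than other genes, and fatty acid synthesis had a negative median with a mean of 0.07. Of markers of other cell types, 2 fibroblast, 2 immune and 0 endothelial genes were measured in this fit.

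Across 14913 genes the changes of the 2 hairpins had Pearson r = 0.59 and Spearman rho = 0.59, where genes are not independent replicates. Simulations with no effect against the same shared control gave a mean r = 0.51 (range 0.50 to 0.52). The covariance was 0.570 against 0.390 simulated, a difference of 0.180. With sh1196 set against the pCDH control in place of the shared one, r was 0.04 and the covariance 0.047. The share of genes with the same sign was then 50.0%, against 71.3% with the shared control and 66.9% simulated. At a 2-fold limit over 10229 genes, 374 were higher in sh1088 and 1074 in sh1196, with 231 in both, where independent lists would share 39. Lower genes numbered 302 and 1249, with 207 in both, where independent lists would share 37. In the simulations, with the genes of largest change taken at those same list sizes, a mean of 211 higher genes (range 194 to 225) and 116 lower genes (99 to 137) were in both. The simulated libraries had a common spread, with 800 and 810 genes at least 2-fold higher, unlike the observed 374 and 1074. The excess may come in part or in full from the shared control, which is 1 library and could not be split. Little of the agreement was left without it.

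The second comparison set overexpression against the pCDH control. SLC7A11 had a log2 ratio of 0.68 (95% counting interval 0.62 to 0.73), SLC3A2 -1.01 (-1.05 to -0.97), GPX4 0.76 (0.62 to 0.91) and EIF3D 0.35 (0.21 to 0.49). With the sh control in place of the pCDH control SLC7A11 stood at -0.70, SLC3A2 at 0.44 and GPX4 at -1.38. By the authors' TPM SLC7A11 was at 80.5 in the pCDH control and lower, at 40.75, in the overexpression library. FPKM gave 103.4 and 75.8 in the same order. The median log2 ratio of all genes (pseudocount 1) was -0.71 by TPM and -0.25 by FPKM, and SLC7A11 by TPM stood at -0.97. The rise of SLC7A11 thus depends on the unit. Over nuclear protein-coding genes the ratio was lower for transcripts of higher GC content (Spearman rho = -0.57 across 10340 genes, against 0.03 and 0.13 for sh1088 and sh1196). Against the sh control the rho of overexpression was -0.12 across 9637 genes. The SLC7A11 transcript has 35.4% GC, and its ratio lay at the 47.6th percentile of the 500 genes nearest in GC content, whose median was 0.71. With the GC trend taken out, a correction chosen after seeing the data, it stood at -0.06. RBMS1 lay at the 51.6th percentile of its GC neighbours (0.12 with the trend taken out) and GPX4 at the 98.4th (1.61). SLC3A2 lay at the 25th percentile (-0.49 with the trend taken out) and EIF3D at the 72.8th (0.54).

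**Figure D2:**
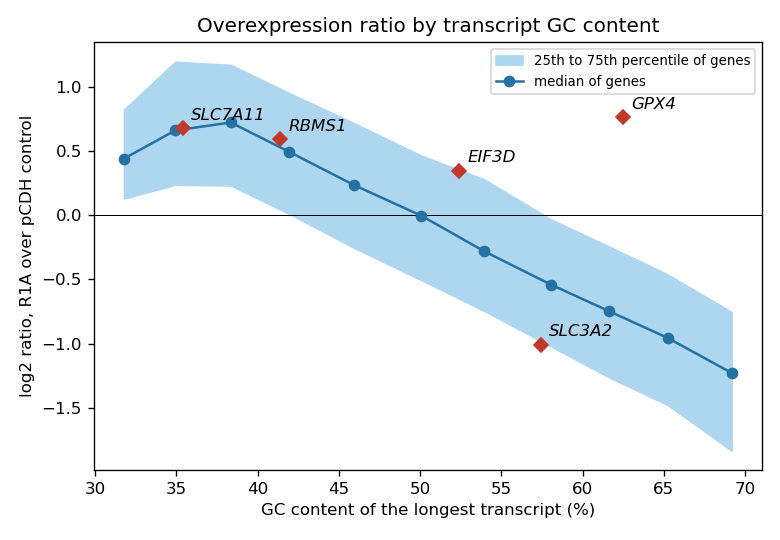
Log2 ratio of overexpression over the pCDH control (y axis) by transcript GC content in percent (x axis), as the median and quartiles of nuclear protein-coding genes per GC bin, with 5 genes as diamonds. The median runs from 0.72 at 38.4% GC to -0.96 at 65.2% GC, and SLC7A11 at 0.68 lies near the median of genes of its GC content.

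This comparison holds 1 library per group, so the differences have no replicate check. Of 10844 genes with mean CPM of at least 5, 1603 were at least 2-fold higher and 1475 at least 2-fold lower. With library size scaling these counts were 1244 and 1848, and by TPM with a pseudocount of 1 they were 352 and 4008, with the median of all genes at -0.71. PI3, an elastase inhibitor, had 437 counts in the overexpression library against 1, a log2 ratio of 7.58 (6.85 to 14.6). SLC6A14, an amino acid transporter, had 118 counts against 0, SNURF 214 against 0, and SNORD110 160 against 0. RPPH1 had 302579 counts against 0 in the pCDH control, where AL355075.4, which overlaps it, held 15.0% of all counts. RN7SL2 was lower at -4.83 (-5.15 to -4.57), and FAM209A had 0 counts against 260. Of the 24 genes named, 22 overlap another gene on the same strand.

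The NF-kB inflammation list had a median log2 ratio of 1.99, above 99% of matched random lists, with 12 of 19 members at least 2-fold higher. SOD2 stood at 2.54 (2.41 to 2.69), CCL2 at 1.99 (1.86 to 2.13) and ICAM1, an adhesion molecule, at 1.07 (0.65 to 1.55). The interferon response list stood at 1.02 with 14 of 27 at least 2-fold higher, while HLA-B and HLA-C were lower at -1.74 and -2.23. Also above the 99th percentile were the proteasome at 0.82, nuclear oxidative phosphorylation genes at 0.80, NRF2 targets at 0.67, G2/M genes at 0.65 and small noncoding RNA at 1.42. The small noncoding RNA list was split, with 6 of 10 members at least 2-fold higher and 4 at least 2-fold lower, 2 of the 10 at 0 counts in 1 library, and RN7SL2 at -4.83. Below the 1st percentile were immediate early genes at -1.06, with FOSB at -1.96 and ATF3 at -1.66, lung lineage genes at -0.96, mesenchymal genes at -0.69, with CCN2 at -2.35 and AXL at -1.32, and the unfolded protein response at -0.60, with MANF at -1.80 and CRELD2 at -1.63. With the GC trend taken out immediate early genes stood at -0.42 (percentile 3.75) and lung lineage genes at -0.21 (percentile 26.3), no longer below the 1st percentile. With the sh control in place, 1 of these 11 lists kept its direction beyond those percentiles, G2/M at 1.40. The NF-kB list then stood at 0.05, with SOD2 at -1.19 and CCL2 at -0.30, and in knockdown against the pCDH control the same list stood at 1.65.

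**Figure D3:**
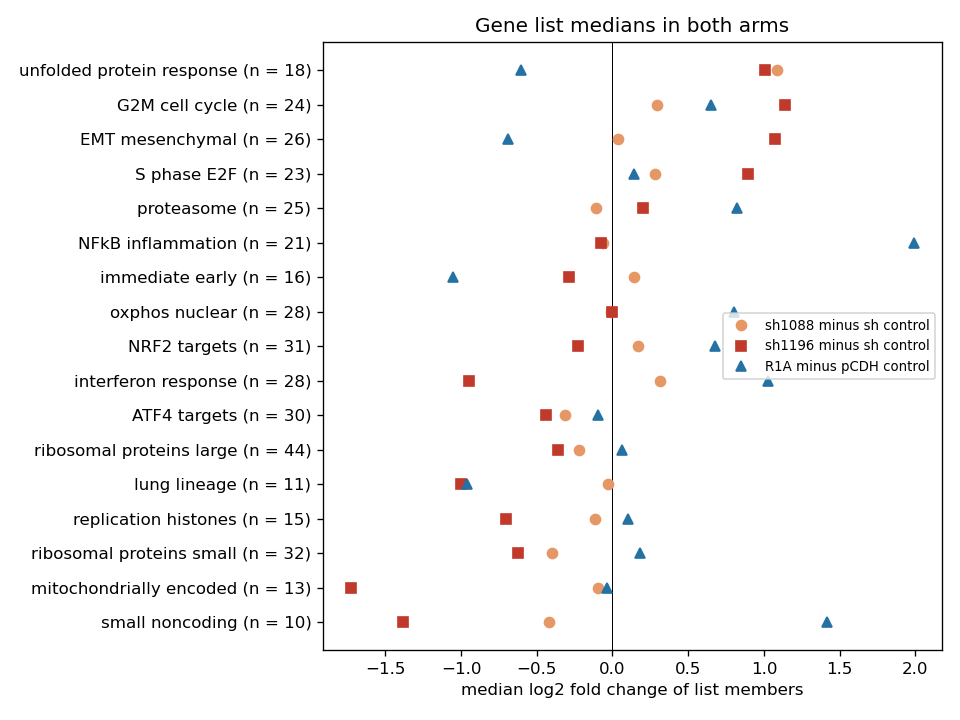
Median log2 fold change of list members (x axis) for each hairpin against the sh control (circles and squares) and for overexpression against the pCDH control (triangles), by gene list (y axis, with the number of members tested in knockdown). The unfolded protein response lies at 1.09 in sh1088, at 1.00 in sh1196 and at -0.60 in overexpression.

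The third comparison asked which genes follow the RBMS1 level over all 5 libraries. Of 15827 genes, edgeR called 1, AC093010.3 (adjusted p = 0.0131), a noncoding gene that overlaps ZBTB20, with 31.4 CPM in the sh control, 0 in both knockdown libraries, 0 in the pCDH control and 4.89 in the overexpression library. At an unadjusted p under 0.05 there were 1046 genes, DESeq2 called 55 and limma-voom 0. SLC7A11 stood at 1.00 per level (SE 0.42, adjusted p = 0.729) and RBMS1 at 0.80 (SE 0.38, adjusted p = 0.729). SLC3A2 stood at -1.07 (SE 0.48), GPX4 at 0.79 (SE 0.39) and EIF3D at 0.08 (SE 0.38). Among the other genes named by rule, none of which passed, PTP4A1 stood at 3.58 and the mitochondrial tRNA gene MT-TF at 2.17, while COL6A2, a collagen chain, stood at -3.16, HLA-B at -2.12 and EID3, which overlaps TXNRD1, at -2.56. Of 33 lists tested in this fit 10 passed camera, 7 higher and 3 lower with the RBMS1 level. With an estimated correlation 0 passed, a test with little power at 2 residual degrees of freedom. Leaving out 1 library at a time gave between 0 and 136 calls, with 40 without the sh control, 136 without sh1088, 30 without sh1196, 0 without the pCDH control and 4 without the overexpression library.

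Across 10609 genes the knockdown and overexpression changes, which share no library, had r = -0.11 and rho = -0.12, and 53.7% of genes had opposite signs. Of 535 genes with an unadjusted knockdown p under 0.05, 316 had the opposite sign in overexpression (59.1%, exact binomial interval 54.8% to 63.3%, as a description, since genes are not independent). With the GC trend taken out r was -0.08, and by TPM with a pseudocount of 1 it was -0.04.

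The authors' deposited table for knockdown calls 539 genes, 263 higher and 276 lower, and its log2 fold changes had Spearman rho = 1.00 with the edgeR ones. In the authors' deposited table SLC7A11 stands at -1.22 (DESeq2 adjusted p = 0.0036) in knockdown and at 1.03 (DESeq2 adjusted p = 0.00181) in overexpression. Neither adjusted p can be taken as a replicated test here. All 539 knockdown calls were shared by DESeq2 with a doubled sh control column, and 13 with each library given once. A copied column adds no replicate. The overexpression table gives a mean above 0 to 1406 genes without counts in either library, so it rests on further input not analysed here. The authors' deposited table for overexpression calls 4503 genes, 2429 higher and 2074 lower, with rho = 0.94 against the ratios computed here.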

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

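Tests of the doubled control, of DESeq2 alone, of exchanged controls, of the sh control alone, of the paired change after GC correction and of both lists by hairpin were chosen only after the result was seen. In the authors' deposited table for overexpression, 1406 genes with 0 counts in both libraries have a normalised mean above 0, and all 1406 means are whole multiples of 0.473 (tolerance 0.001). That table therefore rests on more than these 2 count columns, and its further input was not analysed here.

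The authors' deposited table for knockdown calls 539 genes where the edgeR fit of the 3 libraries called 0. DESeq2 with each library given once shared 13 of those calls, which argues against the choice of tool alone. With the sh control column given 2 times, DESeq2 shared 539 of 539 calls, with a maximum log2 difference of 8.39e-10. A doubled control column is a candidate explanation for the length of that table. A copied column adds no replicate, so its adjusted p-values would then rest on less spread than the libraries hold.

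In overexpression 11 lists lay beyond the 1st or 99th percentile, limits set after the uncorrected percentiles had been seen. With the GC trend taken out 9 of 11 stayed, and with the length trend taken out 10 of 11 stayed, which argues against either trend as the whole cause. Immediate early genes moved to -0.42 (3.75th percentile) and lung lineage genes to -0.21 (percentile 26.3) with the GC trend out, so those 2 lists may owe their place to it. With the sh control in place of the pCDH control 1 of 11 stayed. A pCDH control library that differs from the others is a candidate explanation (in knockdown against it the NF-kB list stood at 1.65), and an effect of RBMS1 or of the vector remains open, since each group holds 1 library.

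The unfolded protein response list was higher in both knockdown libraries (1.09 in sh1088, 1.00 in sh1196). With the GC trend taken out its median was 1.11 (bootstrap interval over members 0.48 to 1.41), and the lower bound fell under the 0.55 set in advance. Without the correction the interval was 0.51 to 1.48, already reaching under that bound, so that test could not decide on GC content. A test added after that outcome, the paired change of the median, gave 0.01 (-0.15 to 0.09), and the list passed camera at the preset correlation (adjusted p = 0.000988), while without the correction it had adjusted p = 0.951 with an estimated correlation and 0.970 by fry. The interval of the paired change holds no fall that would bring the median near 0.55, which argues against GC content as the cause of the rise in these 18 genes. Other mRNA of secreted and membrane proteins (47 genes) had a median of 0.69 (0.49 to 0.77), above the 0.55 set in advance. By that rule a shift of all such mRNA may account for the pattern, though the interval reaches under 0.55. By hairpin, a split made after the result was seen, the medians were 0.34 (0.15 to 0.43) in sh1088 and 1.00 (0.80 to 1.19) in sh1196. Such a shift may then account for the pattern in sh1196 and leaves most of it open in sh1088. Against the pCDH control the medians were 0.66 (-0.04 to 1.28) in sh1088 and 0.25 (0.02 to 0.82) in sh1196, so a low sh control library and an effect of knockdown cannot be told apart with 1 library per control.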

How the results depend on the processing

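Tests with a GC or length correction, a doubled control column, exchanged controls, rescaled TPM or no overlapping genes, and list tests with the other arm's control alone, were chosen only after the result was seen, and the cause was not tested for the changes given here. Knockdown calls by edgeR (0) became 27 with library size scaling, which moves the median of all genes to 0.53, 102 with no low-count filter, 6 at mean CPM of at least 5, 17 by DESeq2, 4 with protein-coding genes alone, 93 against the pCDH control, 1 with the GC trend out and 539 by DESeq2 with the doubled control. Calls of the level fit (1) became 36 with library size scaling, 89 with no filter, 2 at mean CPM of at least 5, 55 by DESeq2, and 0 by limma-voom, with protein-coding genes alone, without the vector term or with the GC trend out. Leaving out 1 library at a time gave 0 to 136. The overexpression counts of 1603 higher and 1475 lower genes became 264 and 203 at 4-fold, 3120 and 2684 at 1.5-fold, and 352 and 4008 by TPM with a pseudocount of 1. The lower count became 2373 at mean CPM of at least 1 and 893 with the GC trend out, and the higher count 840 against the sh control. The log2 ratio of mean RBMS1 CPM in knockdown, -0.97, turned to 1.31 by TPM, 0.70 by FPKM (medians of all genes 1.36 and 0.73) and 0.24 by rescaled TPM, and in overexpression 0.58 became 0.12 by TPM and 0.84 by rescaled TPM. The correlation of the hairpins (0.59) became 0.56 with library size scaling and 0.044 with sh1196 against the pCDH control, and that of the arms (-0.11) became -0.076 with the GC trend out, -0.044 by TPM with a pseudocount of 1 and -0.16 with controls exchanged. Of the 9 knockdown lists that passed, 0 passed by camera with an estimated correlation or by fry, tests with little power at 1 residual degree of freedom. With both controls together 4 lists passed, the unfolded protein response and G2/M from among the 9, and NF-kB inflammation 0.40 and lung lineage -0.60 from outside them, and of the 11 overexpression lists 1 stayed against the sh control. Named genes whose knockdown value reversed against the pCDH control were SLC7A11 0.11, SLC3A2 -0.36, GPX4 1.31, NME1-NME2 -1.51, INO80B -0.58, AL360012.1 16.77 (0 counts in the pCDH control, so this fitted value is no bound), PTP4A1 2.24, SNHG25 0.83, SNORA17B 2.21, PRSS16 2.30, RNY1 0.21, DHODH -1.30, KEAP1 -0.44, POR -1.20, ALDH1L2 2.89, PDIA4 -0.013, RPLP1 0.067, RPL30 0.72, RPS18 0.62, RPS20 1.09, RPS15A 2.10, RPS27A 0.71, MT-ND4L 0.98, MT-ATP6 0.22, MT-ATP8 0.58, MT-ND3 0.76, KIF20A -0.34, CDT1 -0.036, CCNE1 -1.54, MCM5 -0.77, HIST1H2AC 0.25, HIST1H2BC 0.44, HIST2H2BE 1.18 and RNU4-1 3.30. With both controls together NME1-NME2 -0.53, DHODH -0.54, POR -0.58, CCNE1 -0.72 and MCM5 -0.13 reversed. Knockdown lists whose direction relative to other genes (camera) reversed had, against the pCDH control, medians of ferroptosis suppressors 0.096, ferroptosis promoters 0.20, NRF2 targets 0.11, ATF4 targets 0.77, large ribosomal proteins 0.37, small ribosomal proteins 0.54, other translation factors 0.28, nuclear oxidative phosphorylation 0.66, mitochondrial mRNA 0.59, cholesterol synthesis -0.48, S phase -0.34, interferon response 0.86, mesenchymal genes -0.098, cytoskeleton and adhesion 0.028, immediate early genes -0.69, histones 0.30, nuclear noncoding RNA 0.36 and small noncoding RNA 2.92. With both controls together these were ferroptosis suppressors 0.10, ferroptosis promoters 0.095, ATF4 targets 0.12, nuclear oxidative phosphorylation 0.28, cholesterol synthesis -0.21, interferon response 0.17, immediate early genes -0.30 and nuclear noncoding RNA 0.057, and with library size scaling ferroptosis suppressors 0.56 and fatty acid synthesis 0.62. Overexpression genes that reversed against the sh control were SLC7A11 -0.70, SLC3A2 0.44, GPX4 -1.38, RPPH1 -0.26, AL360012.1 -1.66, INO80B-WBP1 -1.67, AC008878.3 -0.20, PDIA4 0.10, HLA-B 1.34, IFITM3 -1.01, HLA-C 0.35, IFIT3 -0.068, SOD2 -1.19, CCL2 -0.30, AXL 0.81 and FOSB 0.10, with the lists nuclear oxidative phosphorylation -0.020, interferon response -0.089, mesenchymal genes 0.11 and small noncoding RNA -1.60. By TPM with a pseudocount of 1, which puts the median of all genes at -0.71, SLC7A11 -0.97, GPX4 -0.00824, EIF3D -0.23, IFITM3 -0.67, NFKB2 -0.64 and ZEB2 -1.17 reversed in sign, SLC7A11 and ZEB2 lying below that median and the others above it. With the GC trend out SLC7A11 -0.061 and ZFP36 0.31 reversed in sign, and with library size scaling IFITM3 -0.036. In the level fit without the vector term GPX4 -0.20, AL139011.2 0.12 and METTL7B 0.15 reversed, and EIF3D (0.082) stood at -0.32 with library size scaling and between -0.15 and 0.33 when 1 library at a time was left out. Summed over alternatives other than leaving out a library, named genes in knockdown kept direction and side of the threshold 746 times, newly passed it 115 times (49 of them with the doubled control column) and reversed 39 times, and those of the level fit 171, 35 and 4 times, with 4 calls lost in the same direction. With 1 library left out, named genes of the level fit kept both 81 times, newly passed 20 times, lost the call 2 times and reversed 2 times. Knockdown lists kept both 130 times, newly passed 5 times, lost the call 29 times and reversed 28 times. Overexpression lists kept their place 20 times, lost it 9 times and reversed 4 times. Named overexpression genes stayed within their counting interval 118 times, left it in the same direction 90 times and reversed 25 times. With either knockdown library left out there is no test, and the naming rule itself favours a sign shared by both hairpins. In simulations at the depth and design of the knockdown comparison 2.69% of 2-fold changes were called, so most changes of that size would be missed, and depth itself was not varied.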

Other observations

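The medians of secreted and membrane protein mRNA by arm were chosen only after the result was seen. The mRNA of secreted and membrane proteins outside the fixed lists had median log2 fold changes of 0.34 in sh1088, 1.00 in sh1196 and -0.49 in overexpression, over 47 of 62 genes written down for the purpose. This difference between the arms was not tested, and each arm has its own control.

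PTP4A1 had 271 CPM in the sh control against 17.5 in sh1088, 10.5 in sh1196, 2.99 in the pCDH control and 16.4 in the overexpression library. MT-TS2, a mitochondrial tRNA gene, had 27290 CPM in the sh control, 6860 in sh1088, 1886 in sh1196, 456 in the pCDH control and 2081 in the overexpression library.

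Over 10054 protein-coding genes the sh control correlated with sh1088 at 0.93, with sh1196 at 0.84 and with the pCDH control at 0.75. The overexpression library correlated with sh1196 at 0.91, with sh1088 at 0.90 and with its own pCDH control at 0.82. These are correlations across genes, which are not independent replicates, and the 2 controls were the farthest apart of these pairs.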
